A study of Homo sapiens with 4 samples.

How the data were processed

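HPB-ALL cells, an established human T cell acute lymphoblastic leukaemia (T-ALL) line, were infected with a lentivirus. It carried either a short hairpin RNA against TLX3 (shTLX3) or the luciferase control construct of the same pLKO.1 vector, per the labels' protocols. The labels name 1 hairpin against TLX3, so its effects on other transcripts could not be separated from the loss of TLX3. The virus was produced in HEK293T cells, a human embryonic kidney line, and infection was by spinoculation. Infected cells were kept in puromycin for 5 days and passed over ficoll, which removes dead cells, on the day before use. Total RNA was purified with RNeasy columns, converted to biotinylated cRNA and hybridised to Affymetrix U133 Plus 2 arrays, on which each transcript is read by 1 or more probe sets. Groups and replicate numbers were taken from the sample titles, which gave 2 control arrays and 2 shTLX3 arrays. The protocols speak of duplicate experiments without saying which step was repeated, so the p-values measure the spread between these arrays, which may be partly technical.

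The values used were the authors' deposited table of intensity, 1 summarised signal per probe set and array on a linear scale. Its positive, skewed values and similar medians showed the linear scale and some scaling between arrays. The summarisation and normalization software was not given in the sources used here, so background subtraction, the scaling method and any lower bound remain unknown. The lowest value on any array was 62.9, and no detection calls were used. How far background signal enters the fold changes of weakly expressed genes is therefore unknown.

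The table held 54675 probe sets, of which 62 control probe sets were left out of the comparison. Intensities were transformed as log2(value + 16), and fold changes are on that scale, where the offset makes those of low genes smaller. Probe sets with a mean below the median of all probe sets (an intensity of 173.8) were not tested, which left 27307. Each was fitted with limma 3.58.1 in R 4.3.3, with shTLX3 minus control as the contrast and an intensity trend in the empirical Bayes step. Residual degrees of freedom were 2 and prior degrees of freedom 8.16. Adjusted p-values are Benjamini-Hochberg values over the probe sets tested, with 0.05 as the threshold.

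Gene names came from the platform annotation, checked against current symbols by gene identifier in a table of human RefSeq genes. 41091 probe sets had 1 symbol, 1801 had several and 11721 were not assigned to a listed gene. A gene was represented by its 1-symbol probe set with the highest mean over all 4 arrays. No genomic coordinates are given, because no genome build was named for these probe sets.

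The 22 gene lists, the comparison, the test, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took TLX3; RUNX1, BCL11B, MYC, NOTCH1 and PTCRA; the 12 largest rises and 12 largest falls past the threshold whose arrays did not overlap between groups; and in each list up to 4 members past the threshold with the largest absolute fold change. RUNX1 had no probe set with 1 symbol and has no value here. Any other gene named was chosen after its values were seen. Of the list members, 74 lay below the intensity filter and 54 had no 1-symbol probe set. Whether a list was shifted against all other genes was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation was run beside it, as was fry, which asks whether a list's own members move one way on balance. With an estimated correlation, camera's test has only the 2 residual degrees of freedom. Few lists can pass it, so a call lost there does not show that correlation between genes explains the shift.

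Alternatives were a replicate block, each array left out in turn, no filter and a stricter filter on dim probe sets, quantile normalization and median centring. Others were offsets of 1 and 64, no intensity trend, a robust trend, a threshold of 0.1, a minimum of 1.5-fold and the mean of all 1-symbol probe sets of a gene. That mean includes probe sets below the intensity filter. The code was tested on simulated data for 27307 probe sets, 200 of them changed. Each was given the mean variance of probe sets of like intensity, so differences in spread among these were not simulated. It recovered 28.4% of log2 changes of 0.25, 97% of changes of 0.5 and 100% of changes of 1, and 8% of its calls were false. None of 20 unshifted simulated lists was called, and a list of 20 genes shifted by 0.3 was found. The noise was drawn independently for each probe set, so these lists do not test the effect of correlation between genes. In the data 11278 probe sets passed the threshold, far more than 200, so the simulated rates need not hold there. Precision is limited by the number of arrays. An exact two-sided permutation of 2 arrays against 2 cannot give a p below 0.333, so every call rests on the spread that limma pools over probe sets.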

Results

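Transcript levels were measured in HPB-ALL cells carrying a hairpin against TLX3, a homeobox transcription factor that is active in this line, and in cells carrying the luciferase control vector. The comparison asked which transcripts differ across the genome once TLX3 is lowered. Each group had 2 arrays. Median intensities were 176 and 171.1 on the control arrays and 173.8 and 174.1 on the shTLX3 arrays. Across probe sets, which are not independent replicates, the control arrays correlated at r = 0.9963 and the shTLX3 arrays at 0.9977, against 0.9778 to 0.9801 between groups. The median absolute log2 difference was 0.075 between the control arrays and 0.058 between the shTLX3 arrays, and 0.154 to 0.174 between arrays of different groups. Errors of log2 fold changes below are standard errors from limma, errors of intensities are SDs, and n = 2 arrays per group throughout.

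TLX3 fell in the cells carrying its hairpin. Its only probe set read 789.6 and 876.4 in the control arrays and 475.2 and 469.3 in the shTLX3 arrays. The mean went from 833 ± 61.4 to 472.2 ± 4.2, which was 43.3% lower, a log2 fold change of −0.80 ± 0.07 (limma, adjusted p = 1.45e-05). PTCRA, which encodes the invariant pre-T cell receptor alpha chain, rose from 2989.8 ± 260.8 to 5439.1 ± 9.2, a log2 fold change of 0.86 ± 0.06 (adjusted p = 3.06e-06). MYC, a transcription factor that drives growth, fell from 7384.6 ± 129.9 to 5686.9 ± 197.7, a log2 fold change of −0.38 ± 0.04 (adjusted p = 5.25e-05). BCL11B, a transcription factor of T cell commitment, rose by 0.23 ± 0.04 (adjusted p = 0.00101), and 2 of its 3 probe sets passed the threshold. The other passing probe set was dim, at 245.6 and 234 in the control arrays. The one not past it was bright, at 3587.2 and 3713 in the control arrays, and did not move (−0.01, limma adjusted p = 0.9). NOTCH1 was not past the threshold, at −0.05 ± 0.07 (adjusted p = 0.58).

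**Figure D1:**
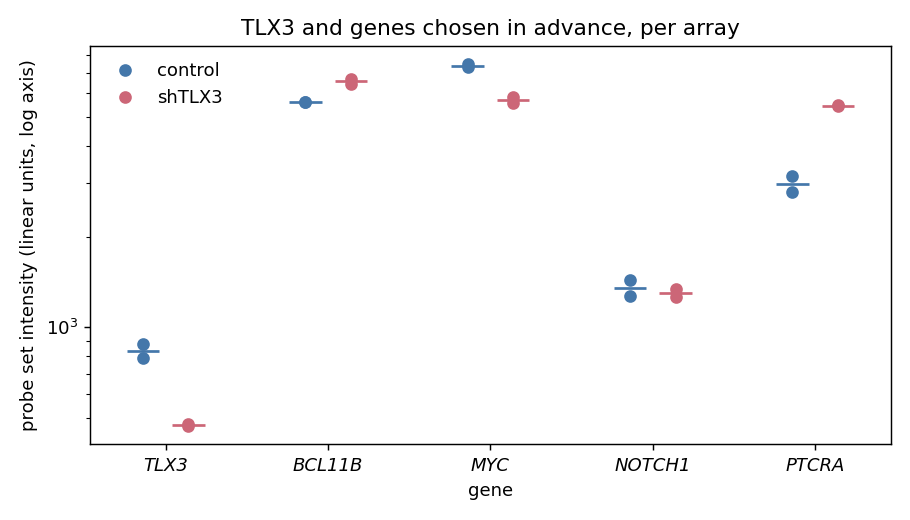
Probe set intensity (log axis, linear units) of TLX3, BCL11B, MYC, NOTCH1 and PTCRA, with 1 point per array (control in blue, shTLX3 in red) and a line at each group mean. Both shTLX3 arrays lie below both control arrays for TLX3 (475.2 and 469.3 against 789.6 and 876.4) and for MYC, above them for PTCRA and BCL11B, and the groups overlap for NOTCH1.

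The largest rises were PFKFB4, ALDOC and P4HA1, all from the hypoxia and glycolysis list. The largest falls were POLR3K, SRM and NOP16, of which SRM and NOP16 are from the MYC target and ribosome biogenesis list. PFKFB4, a regulator of glycolytic flux, rose 6.92-fold, from 254.7 ± 5.5 to 1859.8 ± 127.7 (adjusted p = 1.15e-08). ALDOC, a glycolytic aldolase, rose 5.78-fold, and P4HA1, a collagen prolyl hydroxylase, rose 4.6-fold (adjusted p = 1.15e-08 and 9.85e-09). POLR3K, a subunit of RNA polymerase III, fell from 2234.7 ± 112 to 745.9 ± 12.6, a log2 fold change of −1.56 ± 0.06 (adjusted p = 2.12e-07). SRM, the spermidine synthase gene, and the nucleolar protein gene NOP16 fell, with log2 fold changes of −1.45 ± 0.08 and −1.43 ± 0.06 (adjusted p = 1.2e-06 and 3.61e-07).

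The other large rises were MIR210HG, the host transcript of miR-210 (log2 fold change 2.07), KDM7A (1.81), LGMN (1.78), IGFBP2 (1.76), SNN (1.62), BNIP3 (1.62), IDH1 (1.60), TMEM107 (1.58) and JAM3 (1.53). The other large falls were TMEM201 (−1.41), PNO1 (−1.36), CCDC86 (−1.36), URB2 (−1.26), ZNF521 (−1.25), CMPK2 (−1.24), RTL8C (−1.23), MYBBP1A (−1.22) and RPP40 (−1.21). PNO1, URB2 and MYBBP1A act in the nucleolus and RPP40 is a subunit of RNase P and RNase MRP. In all, 5771 of the 12852 genes tested passed the threshold (44.9%), 2774 higher and 2997 lower in the shTLX3 arrays. Among them, 433 were higher and 446 lower by at least 1.5-fold, and 72 were higher and 47 lower by at least 2-fold. Counted by probe set, 5665 were higher, 5613 lower and 16029 not past the threshold. When all 1-symbol probe sets of a gene were averaged, 34 of the 91 named genes past the threshold moved by more than 1.5 times in log2 fold change. PFKFB4 then stood at 1.55, P4HA1 at 1.09, POLR3K at −0.93, SNN at 0.83, TMEM107 at 0.90, JAM3 at 0.69, NOP16 at −0.75 and PNO1 at −0.71. That mean takes in probe sets below the intensity filter, which can shrink a fold change without disagreement between probe sets. This does not cover PFKFB4, TMEM107 and PNO1, whose probe sets were all above the filter and differed in size. They stood at 2.79 and 0.30 for PFKFB4, and ranged from 0.04 to 1.69 for TMEM107 and from −1.36 to −0.25 for PNO1. The other probe set of P4HA1 read 90.2 and 94.7 in the control arrays and 89 and 91.5 in the shTLX3 arrays.

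**Figure D2:**
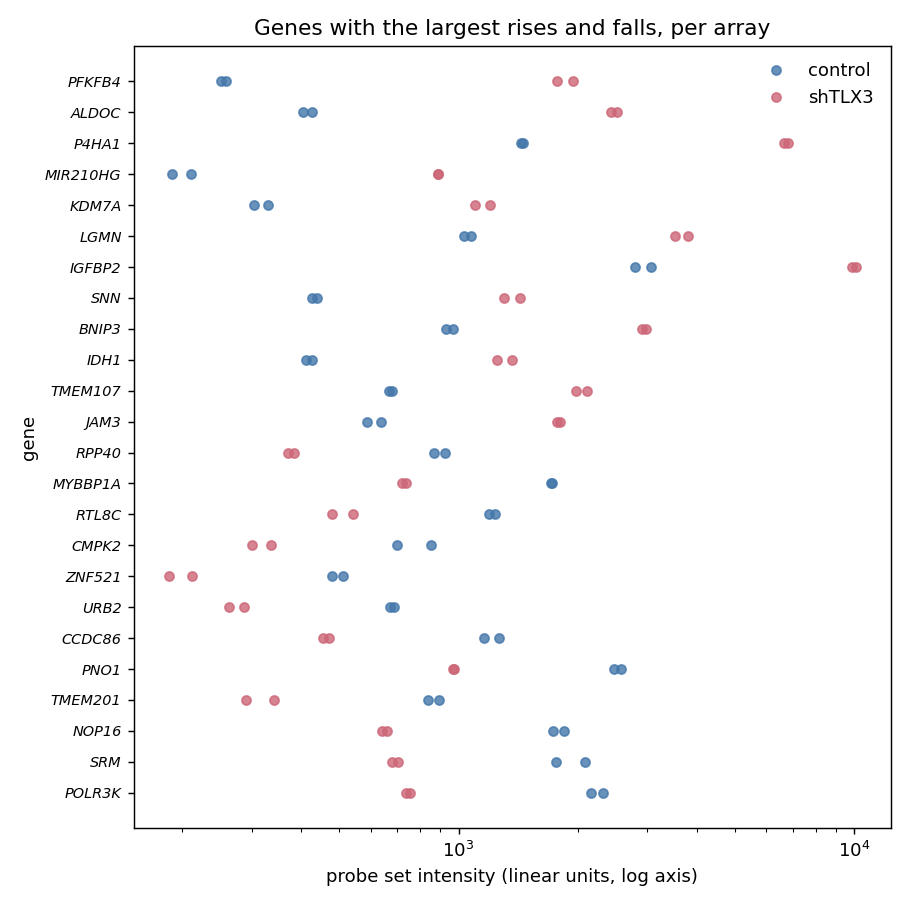
Probe set intensity (log axis, linear units) on each of the 4 arrays for the 12 genes with the largest rises and the 12 with the largest falls (control in blue, shTLX3 in red, 1 point per array). The arrays of the groups do not overlap for any of these genes, which is part of how they were chosen; PFKFB4 goes from a mean of 254.7 to 1859.8 and POLR3K from 2234.7 to 745.9.

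Of 22 hypoxia and glycolysis genes tested, 17 rose, 2 fell and 3 were not past the threshold; adjusted over the list alone, 18 were higher and 3 lower. PFKFB4, ALDOC, P4HA1 and BNIP3, a gene of mitochondrial clearance, led the list. ANKRD37 (−0.75) and SLC2A1 (−0.38), the gene of the glucose transporter GLUT1, fell, while VEGFA (−0.13), SLC2A3 (0.10) and ADM (0.18) were not past the threshold; these 5 were chosen after their values were seen. The list's median log2 fold change was 0.58. It was higher than other genes by camera (adjusted p = 4.86e-10). The call was lost with an estimated correlation (camera adjusted p = 0.415), where the test has 2 degrees of freedom and few lists can pass. The GAPDH control probe sets, which were left out of the comparison, read 19517 and 19910 in the control arrays and 21109 and 20910 in the shTLX3 arrays.

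Of 20 MYC target and ribosome biogenesis genes tested, 19 fell and none rose, and adjusted over the list alone the count was also 19. The list holds genes of ribosomal RNA synthesis and processing, and SRM, NOP16, POLR1B (−1.15), a subunit of RNA polymerase I, and PES1 (−1.04), a factor of the large ribosomal subunit, fell the most. With the mean of their probe sets POLR1B stood at −0.72 and PES1 at −0.51. The member not past the threshold was TFRC, the transferrin receptor gene, at −0.02 (chosen after its value was seen). The median log2 fold change was −0.71 (camera adjusted p = 2.99e-11, and adjusted p = 0.415 with an estimated correlation). The 18S ribosomal RNA control probe sets read 6577 and 4233 in the control arrays and 3549 and 3607 in the shTLX3 arrays, so control array 1 stood apart from the other 3.

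Genes of the T cell receptor complex were mostly higher in the shTLX3 arrays. Of 7 tested, 6 rose, none fell and CD3G (0.04, chosen after its value was seen) was not past the threshold, with 6 higher adjusted over the list alone. After PTCRA, the largest rises were CD3E (0.43), CD247 (0.25) and CD3D (0.22), which encode signalling chains of the complex. The median was 0.22 (camera adjusted p = 0.00481, and adjusted p = 0.415 with an estimated correlation). CD247 was no longer past the threshold when the mean of its probe sets was taken (0.08, adjusted p = 0.175).

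Of 18 genes that act just below the T cell receptor, 12 rose, 1 fell and 5 were not past the threshold, and 13 were higher and 1 lower adjusted over the list alone. THEMIS, needed for thymocyte selection, rose by 1.06, from 1622.9 ± 85.5 to 3405.1 ± 117.4. The adaptor genes SH2D1A (0.63) and LAT (0.54) and the kinase gene LCK (0.51) rose as well. The member that fell was UBASH3B, a phosphatase gene (−0.30, chosen after its value was seen). The median was 0.34 (camera adjusted p = 0.000102, and adjusted p = 0.415 with an estimated correlation).

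Thymocyte stage markers moved both ways: of 24 tested, 11 rose, 4 fell and 9 were not past the threshold, against 13 and 5 adjusted over the list alone. CD69, a marker of activation and positive selection, rose from 607.6 ± 43.1 to 1578.9 ± 33.2 (log2 fold change 1.36), and the surface receptor genes CD6 (0.72) and CD5 (0.69) rose. CD6 stood at 0.17 and CD5 at 0.45 with the mean of their probe sets, and 1 of the 4 probe sets of CD6 tested passed the threshold. CD1A, a marker of cortical thymocytes, fell from 1476 ± 52.2 to 832.5 ± 46.8 (−0.81). CD1D (−0.33), CCR7 (−0.29) and IL7R (−0.16) also fell (chosen after their values were seen). The list as a whole was not called by camera (adjusted p = 0.111).

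T lineage transcription factors were split, with 7 of 23 higher, 6 lower and 10 not past the threshold (8 higher and 6 lower adjusted over the list alone). ETS2 fell from 3873.8 ± 268.4 to 1900.5 ± 7.2 (−1.02) and TCF3, an E protein gene, fell (−0.36). GATA3 (0.49) and ETS1 (0.34) rose. Without shTLX3 array 1, 5 were higher and 3 lower. The list was not called by camera (adjusted p = 0.457). With the mean of its probe sets TCF3 stood at −0.13; 1 of the 10 probe sets of TCF3 tested passed the threshold in the opposite direction, and ETS1 was not past it with the mean of its probe sets (0.09, adjusted p = 0.12).

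NOTCH pathway targets held 9 genes that rose, 3 that fell and 6 not past the threshold among 18 tested, with the same counts of 9 and 3 adjusted over the list alone. The rises were led by BCL6 (0.91), CR2 (0.86), PTCRA and HES4 (0.73), with BCL6 at 0.42 and CR2 at 0.46 when their probe sets were averaged. MYC, SHQ1 (−0.50) and IL7R fell (SHQ1 was chosen after its value was seen). The median was 0.17 (camera adjusted p = 0.0207, and adjusted p = 0.415 with an estimated correlation). With the mean of all probe sets of each gene the list was no longer called (adjusted p = 0.0565).

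Of 15 activation and immediate early genes bright enough to be tested, 9 rose, 1 fell (MYC) and 5 were not past the threshold, and 9 were higher and 2 lower adjusted over the list alone. CD69 led, followed by FOS (0.80), JUN (0.75) and EGR1 (0.74), which encode transcription factors induced within minutes of stimulation. The lower count was 2 without control array 2, with a replicate block, with median centring and with the stricter filter. EGR1 stood at 0.36 with the mean of its probe sets. FOS passed the intensity filter through its shTLX3 values (269.2 and 270.5, against 144.2 and 152.4 in the control arrays). The median was 0.41 (camera adjusted p = 0.00526, and adjusted p = 0.415 with an estimated correlation). The cytokine genes IL2, TNF and IFNG, the receptor gene IL2RA and the transcription factor genes EGR3, NR4A2 and NR4A3 were among 11 members below the filter. Without the filter, 8 of 26 members were higher and 1 lower, and the median was 0.095 (camera adjusted p = 0.00361).

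Mitosis genes past the threshold were mostly higher and replication genes past it mostly lower. Of 24 mitosis and G2/M genes, 16 rose, 1 fell and 7 were not past the threshold (16 and 4 adjusted over the list alone), with BUB1 (0.53), MKI67 (0.47), TTK (0.41) and DLGAP5 (0.31) rising the most. BUB1 stood at 0.25 with the mean of its probe sets. Of 4 MKI67 probe sets tested, 2 passed the threshold, and the others stood at 0.22 and 0.10. CCNB1, the cyclin B1 gene, fell (−0.13, chosen after its value was seen); the lower count was 0 to 3 with 1 array left out and 4 with the stricter filter. The median was 0.18 (camera adjusted p = 0.00481, and adjusted p = 0.415 with an estimated correlation). Of 25 DNA replication and G1/S genes, 11 fell, 1 rose and 13 were not past the threshold, with the same counts adjusted over the list alone. CCNE1, the cyclin E1 gene, fell from 1364.2 ± 87.6 to 755.3 ± 23.8 (−0.84, and −0.46 with the mean of its probe sets), and UNG (−0.51) and CHAF1B (−0.36) fell, while the origin licensing gene CDT1 rose (0.72); 2 were higher after quantile normalization. The median was −0.10 (camera adjusted p = 0.016, and adjusted p = 0.415 with an estimated correlation). The replication call was also lost without shTLX3 array 1 (adjusted p = 0.0754), without shTLX3 array 2 (0.063) and with the stricter filter (0.0645).

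Apoptosis regulators were divided, with 6 of 17 higher, 5 lower and 6 not past the threshold (8 and 5 adjusted over the list alone; camera adjusted p = 0.457). TNFRSF10B, a death receptor gene, rose (0.70), as did BMF, a BH3-only gene (0.59). BAX (−0.56), which promotes cell death, and BCL2 (−0.54), which opposes it, both fell. TNFRSF10B stood at 0.19 and BCL2 at −0.19 with the mean of their probe sets. Of 18 p53 target genes, 8 rose, 3 fell and 7 were not past the threshold (9 and 3 adjusted over the list alone; camera adjusted p = 0.111). TP53INP1 rose from 381.8 ± 0.7 to 1110.1 ± 5 (1.5, and 0.48 with the mean of its probe sets) and CCNG1 also rose (0.73), while AEN fell (−0.70). BAX and TNFRSF10B stand in both lists.

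Interferon stimulated genes held 8 that fell, 3 that rose and 8 not past the threshold among 19, with the same counts adjusted over the list alone (camera adjusted p = 0.457). USP18 (−0.43), IFIT5 (−0.39), IFI44 (−0.38) and IFI35 (−0.37) fell the most, and MX2 (0.33), IFITM1 (0.34) and IRF9 (0.19) rose (the last 3 were chosen after their values were seen). IFI44 was not past the threshold with the mean of its probe sets (−0.12, adjusted p = 0.0779), and IFIT5 stood at −0.23. The stricter filter left 11 members, 3 of them lower. Of the list of T-ALL oncogenes and HOXA genes only 6 were tested, none of them a HOXA gene. Its 6 HOXA genes had no 1-symbol probe set, and TLX1, NKX2-5, TAL2, LMO1, LMO2, LMO3, MEF2C and MEIS1 lay below the filter. PBX3 (−0.35) and LYL1 (−0.26) fell, 4 were not past the threshold and none rose, also adjusted over the list alone (camera adjusted p = 0.419). LYL1 was no longer called without control array 2 (−0.17, adjusted p = 0.104) or without shTLX3 array 2 (−0.23, adjusted p = 0.0954), where 1 member was higher.

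ATF4 and unfolded protein response genes were mixed: 5 of 22 rose, 8 fell and 9 were not past the threshold (5 and 9 adjusted over the list alone; camera adjusted p = 0.324). Without either shTLX3 array, or without the filter, 3 were higher. XBP1, a transcription factor of the unfolded protein response, rose (0.93), and ASNS (−0.64), SDF2L1 (−0.63) and DDIT4 (−0.35) fell. With the mean of their probe sets XBP1 stood at 0.41 and ASNS at −0.36. Of 16 cholesterol synthesis genes, 9 rose, 2 fell and 5 were not past the threshold, with the same counts adjusted over the list alone (camera adjusted p = 0.0797). STARD4 (0.83), SC5D (0.52), LSS (0.29) and MVK (0.29) rose, and ACAT2 (−0.25) and NSDHL (−0.25) fell (both chosen after their values were seen). The lower count was 1 without shTLX3 array 2 and 3 without control array 2. SC5D stood at 0.27 and LSS at 0.15 with the mean of their probe sets. MVK turned direction when its 4 probe sets were averaged (−0.04, adjusted p = 0.499), and 1 of them passed the threshold as lower. Of 14 chemokine, chemokine receptor and integrin genes, 6 rose, 3 fell and 5 were not past the threshold (6 and 4 adjusted over the list alone; camera adjusted p = 0.150). The integrin genes ITGAL (0.87), ITGB1 (0.60, and 0.32 with the mean of its probe sets) and ITGB2 (0.45) rose and ITGA6 fell (−0.30).

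Markers of other cells were measured beside these groups, and their list medians lay low on the scale. Median control intensities were 366 for B cell, 233 for myeloid, 201 for NK and cytotoxic, 258 for erythroid and 274 for epithelial-like markers. Not every member was low, as the control mean was 1460.4 for CR2 and 1780.8 for CDH2. Of 8 B cell markers tested, CR2, CD72 (0.53) and BLK (0.22) rose, none fell and 5 were not past the threshold, with 3 higher adjusted over the list alone. CR2 also stands in the NOTCH list. The B cell list was called by camera (median 0.12, adjusted p = 0.0381, and adjusted p = 0.415 with an estimated correlation). Its median was 0.193 without shTLX3 array 2 and 0.079 over 13 members without a filter. It was not called with a replicate block (0.0518), without control array 1 (0.0523), control array 2 (0.0523) or shTLX3 array 1 (0.0806), with the stricter filter (0.066) or with the mean of probe sets (0.0565). CST3 (0.34) rose among 4 myeloid markers, GZMA (0.58) among 6 NK and cytotoxic cell markers, and HBB (0.23) and EPOR (0.22) among 5 erythroid markers, with no falls in these lists. GZMA passed the filter through its shTLX3 values (254.9 and 248.8, against 159.3 and 166 in the control arrays). Among 5 adherent epithelial-like cell markers, CDH2 fell (−0.30, and −0.17 with the mean of its probe sets) and none rose. Adjusted over the list alone, these 4 lists gave the same counts, and none was called by camera (adjusted p = 0.564, 0.326, 0.457 and 0.783).

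Some of these marker calls did not hold under the alternatives. BLK was not past the threshold without shTLX3 array 1 or array 2, though its log2 fold change stayed at 0.21 and 0.24. CST3 was not past it without shTLX3 array 2 (0.25) or with the mean of its probe sets (0.04, limma adjusted p = 0.48). HBB was not past it without shTLX3 array 1 (0.15) or without a filter (0.23, limma adjusted p = 0.0557). EPOR was not past it without control array 1 (0.21) or shTLX3 array 2 (0.16). The same held for EPOR without a filter (0.225, limma adjusted p = 0.0513) and with the mean of its probe sets (0.08, limma adjusted p = 0.224). A 2nd NK marker was higher without control array 2 or shTLX3 array 2, with a replicate block and with median centring. Without control array 2, 1 myeloid marker was lower, and without control array 1, 2 were higher. 1 epithelial-like marker was higher without shTLX3 array 2, with a replicate block and with either change of filter.

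**Figure D3:**
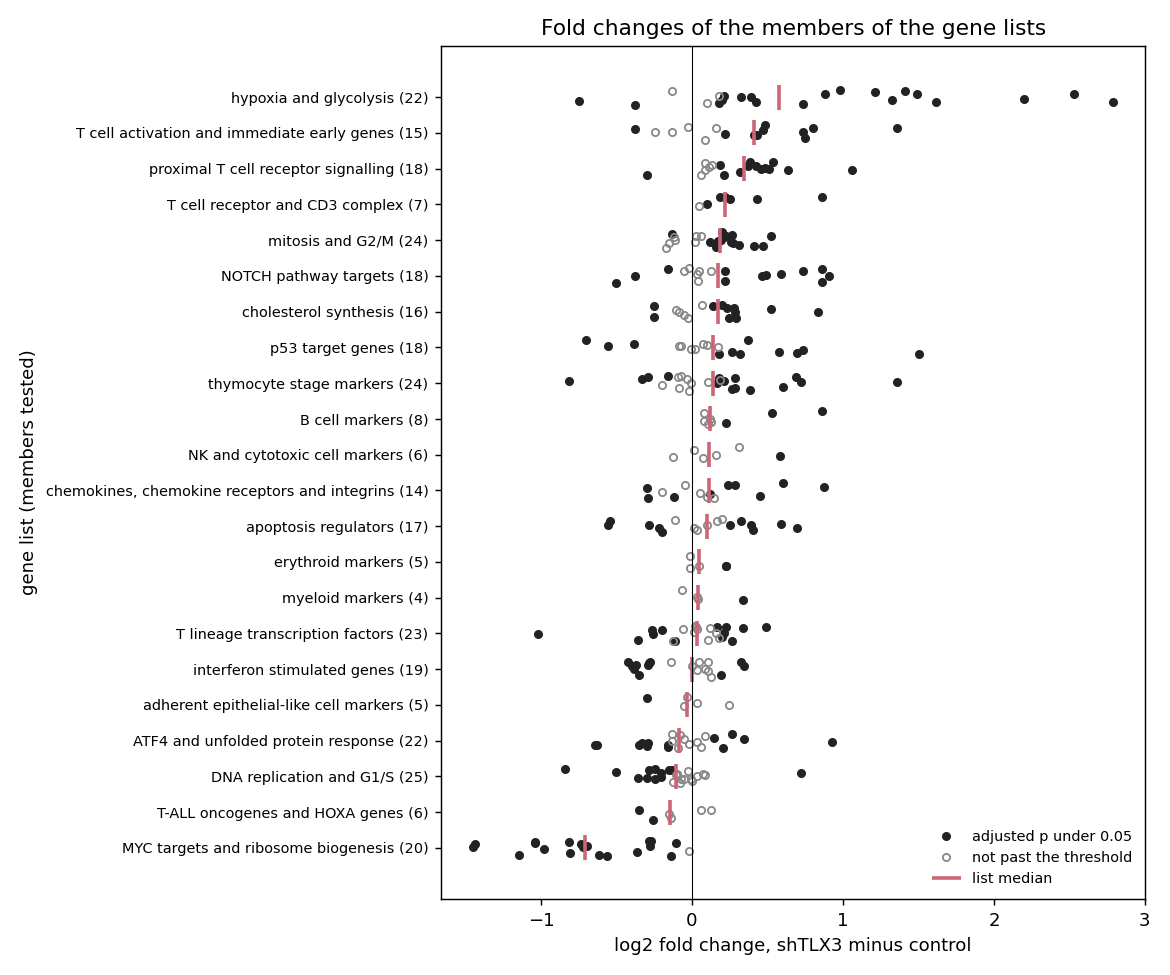
Log2 fold change, shTLX3 minus control, of each tested member of the 22 gene lists (filled points past the adjusted p threshold of 0.05, open points not past it), with a red line at each list's median and the number of members tested in brackets. The hypoxia and glycolysis list has the highest median (0.58) and the MYC target and ribosome biogenesis list the lowest (−0.71).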

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

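The comparison of the control probe sets was chosen after the first results were seen, whereas the fit without a filter had been planned. The GAPDH control probe sets, which lie outside the comparison, were higher on both shTLX3 arrays than on both control arrays. Their mean difference was 0.092 on the log2 scale, against a largest difference of 0.029 between arrays of 1 group, and it was 0.068 after quantile normalization and 0.088 after median centring. The ACTB control probe sets were lower, at −0.16 (14904 and 15363 in control, 13528 and 13596 in shTLX3), and the 18S ribosomal RNA control probe sets too, at −0.56, with a difference of up to 0.63 between arrays of 1 group. These directions held under both scalings. The hybridisation spike-ins, 1191 and 1492 in control and 1601 and 1385 in shTLX3, overlapped between groups.

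Among the 27306 dim probe sets left out of the comparison, 611 were higher and 418 lower in the shTLX3 arrays in the limma fit without a filter, at an adjusted p under 0.05. Among genes represented by such a probe set, MINAR1 had the largest change, from 238.8 ± 14.9 to 108.3 ± 4.9 (log2 fold change −1.03, adjusted p = 5.33e-06). FGFBP2 went from 110.5 ± 5.2 to 204.7 ± 11.6 (0.80, adjusted p = 1.83e-05). Both genes were chosen after their values were seen.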

How the results depend on the processing

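The NOTCH list without MYC (adjusted p = 0.00508) was chosen after the data were seen, and the other alternatives were planned. TLX3 was lower and past the threshold under each alternative that gave it a value, at −0.87 to −0.72 with 1 array left out. The number of genes changed was 4408 to 5905 with 1 array left out, where the lone array of a group is assumed to vary like the other group, and 5733 after quantile normalization, of which 5503 were among the 5771. Requiring at least 1.5-fold left 879 genes (433 higher, 446 lower) and 1649 probe sets. The labels do not say whether equal replicate numbers mark a shared culture or day. Deviations of same-numbered arrays correlated at −0.032 over 27307 probe sets, which shows no strong shared effect but cannot exclude a shared origin. A replicate block gave 5873 genes, 5676 of them shared, and moved the B cell list to 0.05179. Of the other values of named genes under alternatives, 1252 stayed on their side of the threshold with no called value changing direction, 15 were no longer past it, and MVK reversed to −0.0375 with the mean of all probe sets, where other probe sets of the gene went the other way.

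Of the list tests, 280 stayed on their side of the threshold, 19 lost the call and 9 gained one; the cause was not tested except where stated. With an estimated correlation, the calls of the T cell receptor, proximal signalling, NOTCH, MYC and ribosome biogenesis, replication, mitosis, activation, hypoxia and B cell lists were all at 0.4151. That test has 2 degrees of freedom, and its shared value does not tell strong shifts from weak ones. With the mean of all probe sets the NOTCH and B cell lists were both at 0.05653. The replication list was at 0.06445 and the B cell list at 0.06597 with the stricter filter, which tests fewer genes. With 1 array left out, the replication list ranged from 0.02206 to 0.07539 and the B cell list from 0.04484 to 0.08064. Gained calls without a filter were thymocyte markers (0.04932) and cholesterol synthesis (0.02994, and 0.04497 with quantile normalization). Calls gained with fry, which asks another question than camera, were thymocyte markers (0.0312), p53 targets (0.00669), interferon stimulated genes (0.03984), cholesterol synthesis (0.01126), chemokines and integrins (0.03892) and NK markers (0.03948). The stricter filter gave no value for the NK list. Signal over background could not be read from the deposited values.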

Other observations

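The gene families, the second hypoxia list and the MYC targets outside ribosome biogenesis were chosen after the first results were seen, as were the tests of RNA quality, of slower proliferation and of direction by intensity; quantile normalization was planned. Several families of the transcription and protein synthesis machinery, and the proteasome subunits, all taken by symbol, had more members lower than higher in the shTLX3 arrays. RNA polymerase III subunits had 7 of 8 lower and none higher (median log2 fold change −0.53), with POLR3B (−1.17) and POLR3G (−1.07) next to POLR3K. POLR3K, the largest fall, is counted among the 8, and its value was seen before the family was chosen. Of 8 RNA polymerase I subunits 4 were lower and none higher (−0.38; POLR1B also stands in the ribosome biogenesis list), and of 12 RNA polymerase II subunits 9 were lower and 1 higher (−0.25). All 10 UTP genes of the small subunit processome were lower (−0.58), as were 11 of 15 cytosolic aminoacyl-tRNA synthetase genes (−0.29; WARS1 −0.98) and 7 of 11 pseudouridine synthase genes, with 1 higher (−0.43). Mitochondrial ribosomal protein genes had 51 of 74 lower and 4 higher (−0.28), and proteasome subunits 30 of 34 lower and 2 higher (−0.31). Camera called each of these families as lower (adjusted p from 1.1e-10 to 0.00686). The calls were lost with an estimated correlation (camera adjusted p = 0.246 to 0.276), a test with 2 degrees of freedom.

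Cytosolic ribosomal protein genes stood apart from these families, with 2 of 51 higher (RPL3 at 0.16 and RPS3 at 0.08), none lower and a median of 0.03 (camera adjusted p = 0.087). Adjusted over the family alone none was called, and 1 was higher and 1 lower after quantile normalization (median 0) and 1 higher after median centring. Their median control intensity was 19031, near the top of the scale. In the range from 14328 to 22198, 13 of 35 other genes passed the threshold (37.1%), with a median absolute log2 fold change of 0.07 against 0.03 for the ribosomal protein genes. Core histone genes had 10 of 25 higher and 1 lower (median 0.17), led by H2BC21 (1.27), and some probe sets of these near-identical genes may read more than 1 of them; their median was 0.14 with quantile normalization, under which the count of all genes changed was 5733. Complex I subunits had 14 of 32 lower and 3 higher (−0.10, and −0.056 after quantile normalization). Zinc finger genes named ZNF had 118 of 377 higher and 48 lower (0.07), and of 16 tubulin and gamma-tubulin complex genes 2 were higher (1 after median centring) and 2 lower. Camera called the histone, complex I and ZNF families (adjusted p = 0.00686, 0.00686 and 0.00839) but not the tubulins (0.8), and none with an estimated correlation (adjusted p = 0.246, 0.436, 0.246 and 0.884 with an estimated correlation). The directions of the families with a camera call held under quantile normalization and median centring.

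The rise of hypoxia and glycolysis genes may be part of a wider low-oxygen type response. Not every member moved this way: 2 of 22 fell, ANKRD37 and SLC2A1, and VEGFA, SLC2A3 and ADM were not past the threshold. A second hypoxia list of other genes, written without their values, had 18 of 25 higher and 2 lower, STC2 (−0.38) and JMJD6 (−0.20), with a median of 0.403 (camera adjusted p = 1.8e-07, and adjusted p = 0.246 with an estimated correlation). A difference in RNA quality stays open: the 3'/5' log2 ratios of the GAPDH and ACTB control probe sets differed between groups by at most 0.045, but their 3' probe sets read 16773 or more on every array, near the top of the scale, where a ratio changes little. Whether the response follows the loss of TLX3, another effect of the hairpin, or a difference in density or oxygen between the cultures stays open, because each would follow the groups in this design.

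The fall of ribosome biogenesis genes may reflect lower MYC output, as MYC itself fell (−0.38). Cytosolic ribosomal protein genes had none of 51 lower, but they read near the top of the scale, where changes were small. MYC targets outside ribosome biogenesis, also written without their values, had 23 of 24 lower and none higher, with a median of −0.468 (camera adjusted p = 6.65e-12, and adjusted p = 0.246 with an estimated correlation). PRMT3 (−0.86) and CTPS1 (−0.85) led them, and PHB2 (−0.07) was not past the threshold. Slower proliferation stays open. The mitosis list had a median of 0.183 with 16 of 24 members higher (adjusted p = 0.00481 by camera and 0.415 with an estimated correlation), while the replication list went down. These values were known before the question was set, and no growth rate was analysed here, so the lists do not decide it. Lower nutrient or growth signalling in the shTLX3 cultures, which would also lower MYC targets, and a direct effect of TLX3 stay open and were not tested.

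The number of genes changed, 5771, is large for 2 arrays against 2. An array-wide intensity difference stays open as a source of part of it, because the deposited values were already scaled between arrays by a method not given. Over 10 classes of intensity, 44.7% of the genes changed went against the more frequent direction in their class. The class medians, −0.041 to 0.031, lay near no change, so a split close to even can follow from the scaling. Quantile normalization, with 5733 genes called and 5503 of them among the 5771, decides nothing either, as it moved log2 fold changes by a median of only 0.014. The genes changed had a median absolute log2 fold change of 0.334, against a median standard error of 0.068. The threshold selected these genes for size, so that ratio decides nothing. Over all probe sets tested, without that selection, the median absolute log2 difference was 0.154 to 0.174 between arrays of different groups. Within groups it was 0.075 and 0.058. A shift shared by genes of like intensity would move them together, and the class medians lay near no change. Such a shift could not alone give differences of that size. That argues against it as the whole source of the count. A difference in handling between the groups, shared by both arrays of a group, would be counted the same way as an effect of the hairpin, and the labels give no batch with which to part them.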
